A study of Mus musculus with 4 samples.

How the data were processed

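RNA from whole uterus was measured on 4 Affymetrix mouse expression arrays, 1 array per sample. Per the labels, every sample came from a mutant of COUP-TFII, the orphan nuclear receptor encoded by Nr2f2, and 6 µg of total RNA entered the labelling reaction. The labels place 2 arrays in the oil group and 2 in the ICI group. No label says whether replicates came from separate animals, so the p-values measure the spread between these samples, which may in part be technical. No scan date or other batch is given in the sources used here.

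The deposited values are intensities on a linear scale, 1 MAS5 signal per probe set. MAS5, which combines the probe pairs of a set into 1 signal and scales each array to a common target, was named in the submitters' processing notes without a version. The trimmed mean signal, leaving out 2% of probe sets at each end, was 500 on each of the 4 arrays. The deposited values were therefore used with no further scaling. Detection calls were not used here, so a dim signal is described by its place among all signals of the array and not as detected or absent. MAS5 subtracts a mismatch probe signal, which leaves low values noisy.

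The arrays carried 45101 probe sets, of which 64 were controls. Gene names came from the platform annotation. It gave 1 symbol to 34945 probe sets, several to 932 and none to 9160, the controls left aside. Entrez identifiers of 34754 probe sets were found in a gene table of the mouse assembly GRCm38.p6, and this changed 0 symbols. That table served for names only, and no coordinates are printed because the build behind the array design is not given in the sources used here. No gene was named from a probe set with several symbols. Each gene was represented by its probe set with the highest mean value over the 4 arrays, which gave 18193 genes. Genes were kept when their mean log2 value lay above the 40th percentile of all non-control probe sets, a signal of about 68.6. This left 12557 genes and set aside 5636.

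Values were analysed as log2(signal + 16), and all fold changes are on that scale, ICI minus oil, which understates the change of dim genes. Groups were compared with limma (lmFit and eBayes with a trend of the variance on the signal), with no other term in the model. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 2 samples per group left 2 residual degrees of freedom, to which the moderation added 7.99. An exact permutation test of a single gene cannot go below p = 0.333 with 2 samples against 2. As a description with no control of false calls, genes with a fold of at least 1.5 and an unadjusted p under 0.05 were also counted.

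In total 40 gene lists covering hormone responses, pathways and cell types were written before the data were examined, and 39 of them had at least 5 measured members. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Members were also counted after Benjamini-Hochberg adjustment over each list alone. Camera was repeated with the correlation estimated from the data and with ranks, and fry was run as a test of each list by itself. Lists were also set against 10000 random lists whose members were each drawn from the 100 genes nearest in mean signal. That matching replaced a coarser one in signal bins after results had been seen.

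The genes named in the text follow a rule written before the data were examined. It takes up to 12 called genes of largest change in each direction. Where fewer were called, it fills up with genes of unadjusted p under 0.01 whose groups do not overlap, given as values. Genes named only by a clone or predicted locus were left out of this part. It adds 26 fixed genes and, from each list, up to 4 members with the smallest p. Genes named outside the rule are said to be so.

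The scripts were tested on simulated data for ICI versus oil, with 12557 genes, 20 draws and 200 changed genes per draw. With 2 samples per group, 49.8% of genes changed 1.5-fold, 78.6% of those changed 2-fold and 96.8% of those changed 4-fold were recovered. Of the genes called, 5.41% were false. The noise came from the variance model that limma fitted to these data, so this share cannot test that model. A list of 26 genes shifted by 0.4 was found in 20 of 20 draws and an unshifted list in 0 of 20. Lists counted as found at an unadjusted p under 0.05 (camera), without the adjustment over lists used for the real data. The simulated noise was drawn independently for each gene, so these draws cannot show how the tests behave where genes vary together. The correlation between genes estimated from the real data was 0.459 for the mitosis list and 0.27 for the DNA replication list.

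The alternatives tried were quantile normalization, a shift of each array to a common median, offsets of 1 and 64, no filter and a filter at the 60th percentile. Further ones were eBayes without the trend, the replicate number as a block, each array left out in turn, the mean of all probe sets of a gene, and all probe sets as units. Thresholds of 0.1 on the adjusted p and of 2 on the fold were tried too. A fit without probe sets whose suffix (_s_at or _x_at) marks possible cross-hybridisation was added after seeing the data. Analyses used R 4.3.3 and limma 3.58.1, and figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of these comparisons.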

Results

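Whole-uterus gene expression was measured in COUP-TFII mutant mice under a hormone regimen that imitates early pregnancy. Ovaries had been removed, so that the supplied hormones set the estrogen and progesterone levels. Animals received 3 injections of 100 ng estradiol, 2 days of rest, and then 1 mg progesterone with 6.7 ng estradiol daily for 2 days. At 34 h of the combined treatment, oil or ICI 182,780 (fulvestrant) was given for 6 h. ICI 182,780 is an antagonist that blocks the estrogen receptors and promotes their degradation. There were 2 arrays per group. The comparison asks which transcripts of the mutant uterus depended on estrogen receptor activity in this window. No wild-type uterus is part of the design.

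The arrays resembled one another closely. Median signals were 130 and 131 in the oil group and 120 and 127 in the ICI group. Across the 12557 genes tested, the Pearson correlation was 0.988 between the oil arrays and 0.988 between the ICI arrays, and 0.984 to 0.986 between groups. Genes are not independent replicates, so these correlations describe the arrays only. The SD of the log2 difference was 0.27 and 0.272 within the groups, against 0.295 to 0.31 between them. The 3' to 5' signal ratio of Gapdh, a measure of RNA integrity, lay between 0.718 and 0.754 on the 4 arrays, and that of Actb between 1.32 and 1.4.

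Among the 13 genes that fell after ICI 182,780 were 3 of the late estrogen-induced list, Prap1, Lcn2 and Ltf, and among the 6 that rose were 4 of the DNA replication list. The largest fall was that of Prap1, a secreted proline-rich acidic protein of uterine and intestinal epithelium, by 5.68 on the log2 scale (SE 0.369, adjusted p = 0.000348, limma). Its signals were 1947 and 761.1 on the oil arrays and 9.45 and 6.67 on the ICI arrays, the latter around percentile 11 of the array. Clca1, a secreted regulator of chloride channels, fell by 3.82 (adjusted p = 0.0102, limma), and Aoc1, a diamine oxidase that degrades histamine and polyamines, fell by 3.42 (adjusted p = 0.0158, limma). Because the ICI signals of these genes were dim, the size of the fall depended on the offset: with offsets of 1 and 64 the log2 change was -6.07 and -4.16 for Prap1, -4.15 and -3.14 for Clca1, and -4.12 and -2.41 for Aoc1. Sftpd, the secreted collectin surfactant protein D, fell by 2.53. Lcn2, the iron-siderophore binding protein lipocalin 2, fell by 2.23. Ltf, encoding the iron-binding secretory protein lactoferrin and a classical estrogen target of mouse uterus, fell by 1.58, from a mean signal of 6253 ± 2918 to 1966 ± 205 (SD, n = 2 per group). The oil arrays differed from each other by more than the ICI arrays for Ltf and Lcn2, with 8316 and 4189 for Ltf and 4375 and 1703 for Lcn2.

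Smaller falls passed the test for 7 further genes. Prune2 fell by 1.26 by its brightest probe set, while the other 3 stood at -0.25, -0.17 and 0.05. Pcdhb9, a clustered protocadherin, fell by 1.05 and Inhbb, the inhibin and activin beta B subunit, by 0.94, while a second Inhbb probe set stood at -0.17. Calb2, the calcium-binding protein calretinin, fell by 0.93, and the lipoxygenase Alox15 by 0.69, with oil signals of 2345 and 2328 against 1443 and 1442. The fatty acid transporter Cd36 fell by 0.58 and Mamdc2 by 0.46, the latter being the 13th called fall and so named outside the rule. The adjusted p-values of these 7 genes ran from 0.00547 to 0.0471 (limma). Without ICI replicate 2 Cd36 and Mamdc2 did not pass, nor did Mamdc2 without ICI replicate 1.

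Of the 6 genes that rose, most act in S phase. Uhrf1, which couples maintenance DNA methylation to replication, rose by 0.90 on the log2 scale (SE 0.111, adjusted p = 0.0169, limma), from signals of 474.8 and 496.1 to 959.7 and 877. The replicative helicase subunits Mcm6 and Mcm5 rose by 0.72 and 0.52, and Rrm2, the small subunit of ribonucleotide reductase, by 0.58. Tcf19, a gene induced at the G1/S transition, rose by 0.68, and the mitotic kinesin Kif22 by 0.78. For Kif22, Rrm2 and Mcm5 the brightest probe set was of a kind that can cross-hybridise, and without such probe sets their log2 changes were 0.37, 0.27 and 0.31 and did not pass. Mcm5 did not pass without ICI replicate 2 either. The rule added 6 genes that did not pass, given as values. Tnnt2, cardiac troponin T, stood at 1.36 (adjusted p = 0.0827, limma), Prr11 at 1.17, Ube2t at 1.16, Tmprss11a at 1.06, Gatb at 1.04 and Shisa4 at 0.97.

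**Figure D1:**
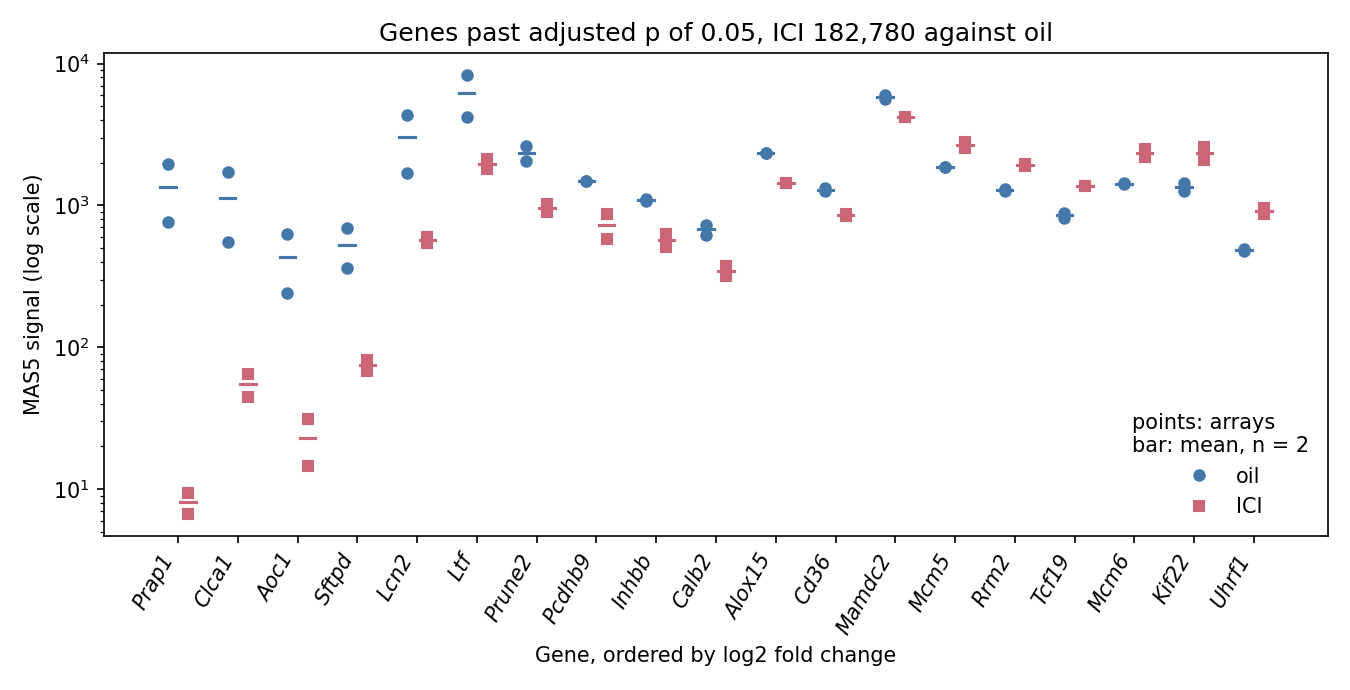
MAS5 signal on a log axis of the 19 genes past an adjusted p of 0.05, ordered by log2 fold change; circles are the 2 oil arrays, squares the 2 ICI arrays, and bars the group means. Prap1 lies at 1947 and 761.1 on the oil arrays and at 9.45 and 6.67 on the ICI arrays, while the genes that rose, at the right, differ by less than the largest falls.

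In all, 19 genes passed, 6 higher and 13 lower after ICI 182,780. Shifting each array to a common median gave 38, with 18 higher and 20 lower. At an unadjusted p under 0.05 there were 1296 genes, where chance alone would give 628. A fold of at least 1.5 with that p was met by 111 genes that were higher and 133 that were lower, a split that became 143 and 99 with quantile normalization. The groups did not overlap for 41.7% of genes, against 33.3% by chance. The count of called genes depended on the settings. It was 0 by eBayes without the trend, with 1132 genes at an unadjusted p under 0.05. With either no filter or the mean of a gene's probe sets it was 1. It also moved with single arrays, to 38 without ICI replicate 1, 60 without ICI replicate 2, 60 without oil replicate 1 and 133 without oil replicate 2.

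Most of the measured cell cycle genes were higher after the antagonist. All 26 measured members of the mitosis list had higher means after ICI 182,780, with a median log2 change of 0.49, and 20 rose when adjusted over the list alone, against 0 over all genes tested. Among them were the cytokinesis genes Anln at 0.73 and Prc1 at 0.62, the anaphase activator Cdc20 at 0.71 and cyclin A2 (Ccna2) at 0.73. Mki67, the proliferation marker, was also among them, at 0.49 with signals of 1441 and 1663 against 2236 and 2117. Of 30 DNA replication genes 27 were higher, with a median of 0.39. Of these, 20 rose when adjusted over the list alone and 4 over all genes tested (Uhrf1, Mcm6, Rrm2 and Mcm5). Mcm2 did not pass, at -0.13, and its other probe set stood at 0.34. The adjusted camera p was 2.97e-23 for mitosis and 6.5e-19 for DNA replication, and with an estimated correlation the adjusted p was 0.379 for both. The number of mitosis genes that rose was 10 without ICI replicate 1, and that of replication genes was 13 without ICI replicate 2. Relative to the oil mean, mitosis members averaged 0.61 on ICI replicate 1 and 0.39 on ICI replicate 2.

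Genes that estradiol induces late in the mouse uterus, over many hours, were lower. Of 18 measured, 14 had lower means and 10 fell when adjusted over the list alone, 3 of them over all genes tested (Prap1, Lcn2 and Ltf), with a median of -0.40 and an adjusted camera p of 1.4e-09 (adjusted p = 0.379 with an estimated correlation). The peptidylarginine deiminase Padi2 was among the 10, at -0.90. The list of early estrogen-induced genes had a median of -0.09 and an adjusted p of 0.000133 (0.379 as the adjusted p with an estimated correlation). When adjusted over that list alone 8 of 24 fell and 1 rose, against 1 that fell over all genes tested. Those that fell included Inhbb, the transcription factor Egr1 at -0.47, the Ras-related Rasd1 at -0.48 and the thioredoxin inhibitor Txnip at -0.29. The 1 that rose was Mad2l1, a spindle checkpoint gene that is also on the mitosis list, named here outside the rule. The median of the early list was -0.20 without oil replicate 2 and -0.06 without ICI replicate 1, where 13 were lower and 11 higher. The number that fell was 3 without ICI replicate 1 and 1 without the variance trend, while that of late genes was 6 without the trend. Immediate early genes, transcribed within minutes of a stimulus, had a median of -0.10 and an adjusted p of 0.00212 (adjusted p = 0.379 with an estimated correlation), and 3 of 25 fell over the list alone, Egr1, Ier3 and the orphan receptor Nr4a1 at -0.78. That list no longer passed without ICI replicate 1, at a median of -0.11, and its median was -0.15 without ICI replicate 2, -0.17 without oil replicate 2, -0.06 without a filter and -0.04 with a filter at the 60th percentile, where it was also lost.

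The estrogen targets known from breast cancer cells had a median of -0.02, which turned to 0.02 with quantile normalization, and did not pass (adjusted p = 0.432, camera). Of 29 members 0 fell and 1 rose when adjusted over the list alone, Tpd52l1 at 0.44, and the trefoil peptide gene Tff1 stood at -0.70. The coactivator Greb1, on that list, had a log2 change of -0.02 and cyclin D1 (Ccnd1) 0.00. Over their probe sets above the filter the change ran from -0.31 to 0.08 for Greb1 and from -0.23 to 0.00 for Ccnd1. Members of the early list that did not pass included the growth factor Igf1 at 0.04 and Myc at -0.02, and of the late list the mucin gene Muc1 at 0.31. Adjusted p-values of these 5 genes ran from 0.726 to 1 (limma). Ar, C3 and Areg had no probe set with a single symbol and are not analysed here.

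The transcripts of the hormone receptors themselves did not pass, and receptor protein was not measured on these arrays. Esr1, encoding estrogen receptor alpha, had a log2 change of -0.09 (SE 0.0769, adjusted p = 0.737, limma) and Pgr, the progesterone receptor, of -0.10 (adjusted p = 0.678, limma). Esr2 lay below the filter, with signals from 5.93 to 23.8. Nr2f2 stood at 0.18 (SE 0.0942, adjusted p = 0.548, limma), with signals of 860.5 and 871.6 on the oil arrays and 1010 and 957.8 on the ICI arrays. Its 4 probe sets above the filter disagreed in sign, from -0.67 to 0.18. Because every sample is mutant and the position of the probes relative to the altered part of the gene is not given in the sources used here, this level does not check the labels. The list of steroid receptors and coregulators had a median of -0.04 and did not pass (adjusted p = 0.473, camera).

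Progesterone-induced genes did not pass as a list, with a median of -0.04 (adjusted p = 0.762, camera). Over that list alone 1 of 31 rose, the stromal transcription factor Hand2 at 0.35, and 1 fell, the glutathione peroxidase Gpx3 at -0.28. A second Hand2 probe set stood at -0.15, and over all genes Hand2 had an adjusted p of 0.127 (limma). The hedgehog pathway, through which epithelial Ihh signals to stromal Ptch1, had a median of 0.09 (adjusted p = 0.877, camera), with Ihh at 0.11 and Ptch1 at 0.10. The 3 Ptch1 probe sets ran from -0.06 to 0.44. The growth factors by which stroma signals to epithelium had a median of -0.06, which turned to 0.01 with quantile normalization (adjusted p = 0.713, camera). In that list Fgf1 stood at 0.29, Fgf9 at -0.08, and the receptors Erbb3 and Fgfr2 at -0.41 and -0.22. Fgf2 and Fgf18 lay below the filter. The Wnt pathway had a median of -0.07 (adjusted p = 0.245, camera), with Wnt4 at 0.32. Implantation and decidualization genes passed at -0.09 (adjusted p = 0.0232, camera, and adjusted p = 0.379 with an estimated correlation). The gap junction gene Gjb2, with signals of 468.7 and 256.4 against 169.0 and 163.1, fell over the list alone, as did Foxo1 at -0.31 and Stat3 at -0.27. Lif at -0.05, Bmp2 at 0.09 and Hoxa10 at -0.07 did not. This list was lost without ICI replicate 1, at a median of -0.04, and without oil replicate 1, where the median was larger, at -0.13.

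**Figure D2:**
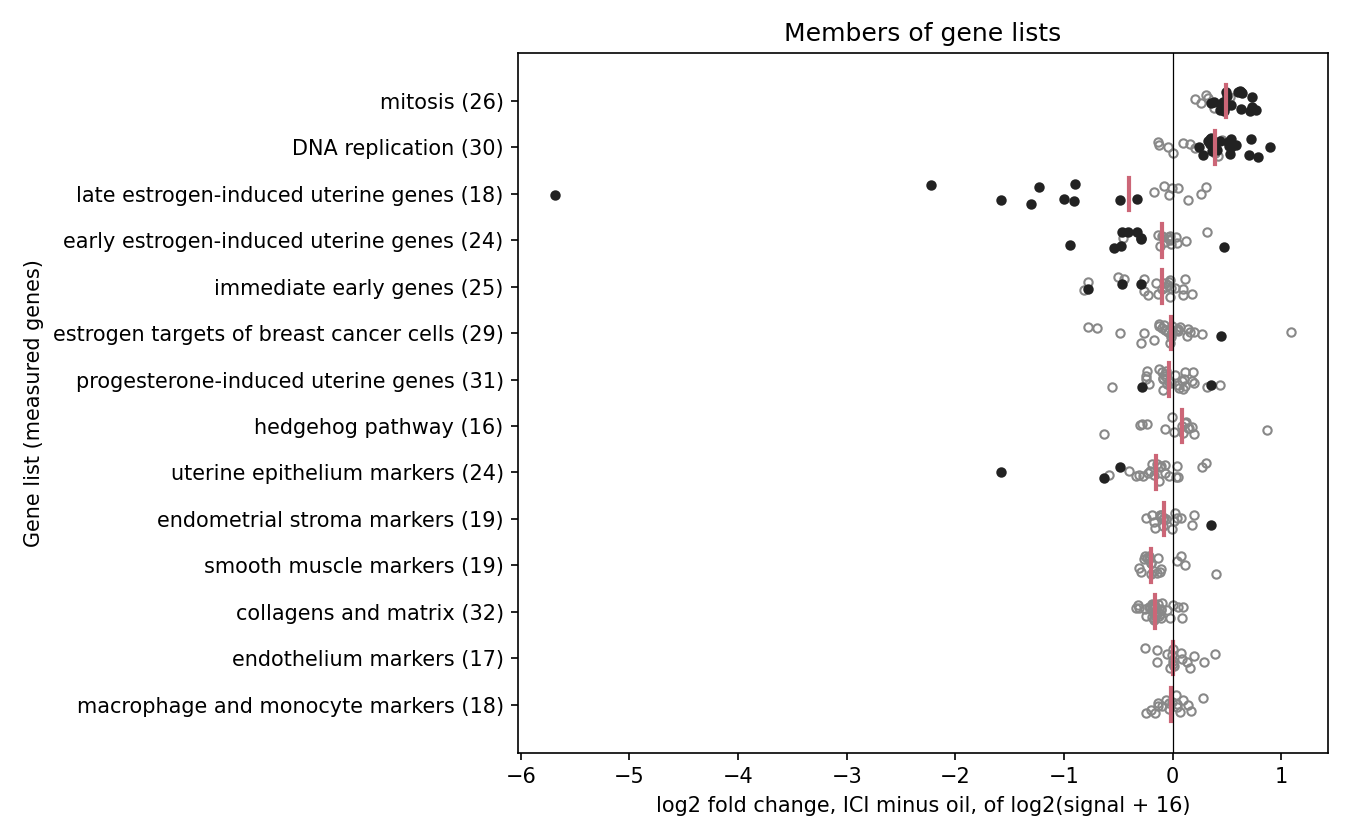
Log2 fold change (ICI minus oil) of each measured member of 14 gene lists; filled points pass an adjusted p of 0.05 over the list alone, open points do not, vertical bars are medians, and counts in parentheses are the measured genes. Mitosis and DNA replication have medians of 0.49 and 0.39, the late estrogen-induced genes a median of -0.40, and the endothelium and macrophage markers medians of 0.01 and -0.02.

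Markers of tissue layers shifted by small amounts beside these groups. Collagens and other matrix genes had lower means for 28 of 32 members, with a median of -0.16 (adjusted p = 1.39e-08, camera, and adjusted p = 0.379 with an estimated correlation), and examples were Col4a2 at -0.25, Col1a1 at -0.25 and Postn at -0.22. Smooth muscle markers were lower for 15 of 19, with a median of -0.19 (adjusted p = 2.89e-05, camera, and adjusted p = 0.379 with an estimated correlation), Myh11 at -0.29 and Actg2 at -0.25. A second Myh11 probe set stood at 0.04, and with quantile normalization the muscle median was -0.11. Uterine epithelium markers were lower for 19 of 24, with a median of -0.16 (adjusted p = 1.75e-05, camera, and adjusted p = 0.379 with an estimated correlation), and Ltf, Elf3 at -0.63 and the matriptase gene St14 at -0.48 fell over the list alone. Mesothelium markers had a median of -0.13 (adjusted p = 0.0234, camera, and adjusted p = 0.379 with an estimated correlation), and only Calb2 of the 9 fell over the list alone. In the design as fixed, 0 matrix and 0 muscle genes passed over their list alone, though 4 muscle genes did with the mean of probe sets. Quantile normalization gave 1 muscle gene, as did leaving out cross-hybridising probe sets. Without oil replicate 1, 9 matrix and 9 muscle genes did, and without oil replicate 2, 7 matrix genes and 1 muscle gene did. Of the epithelium markers 1 passed without oil replicate 1, 1 without ICI replicate 2 and 0 without the variance trend. Their median was -0.24 without ICI replicate 1, and the mesothelium list was lost without ICI replicate 1 and without oil replicate 2, with medians of -0.13 and -0.15. Stroma markers did not pass, at a median of -0.08 (adjusted p = 0.306, camera), nor did endothelium markers at 0.01 (adjusted p = 0.522, camera). Without ICI replicate 2 the endothelium list passed as higher (adjusted p = 0.00675, camera).

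Immune lists were lower in part. The interferon response genes had a median of -0.15, with 21 of 24 lower (adjusted p = 0.000133, camera, and adjusted p = 0.489 with an estimated correlation), and Irf7 at -0.70 was the 1 member that fell over the list alone. Without ICI replicate 2 the median was -0.05. Lymphocyte and NK cell markers had a median of -0.27, with 12 of 13 lower (adjusted p = 0.000581, camera, and adjusted p = 0.535 with an estimated correlation). The cytotoxic proteases Gzma at -0.58 and Gzmb at -0.53 fell over the list alone. The list was lost without oil replicate 1, at a median of -0.14, and its median was -0.40 without oil replicate 2. Complement and acute defence genes had a median of -0.10 (adjusted p = 0.00128, camera, and adjusted p = 0.604 with an estimated correlation). There 3 of 19 fell over the list alone, Lcn2, Ltf and the complement inhibitor Cfi at -0.76. Lcn2 and Ltf are also on the late estrogen-induced list, so this list is not separate from that one. The list was lost without ICI replicate 2, at a median of -0.06, and its median was -0.01 without oil replicate 1, -0.22 without oil replicate 2 and -0.18 without ICI replicate 1. Macrophage and monocyte markers had a median of -0.02 (adjusted p = 0.762, camera), but passed as lower without ICI replicate 1 (adjusted p = 0.0366, camera) and without oil replicate 2 (adjusted p = 0.0228, camera).

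Water and ion transport genes, 15 of 19 lower, had a median of -0.09 (adjusted p = 0.00446, camera, and adjusted p = 0.379 with an estimated correlation), and Clca1 and the carbonic anhydrase Car2 at -0.32 fell over the list alone. The median was -0.16 without ICI replicate 1 and -0.16 without ICI replicate 2. Ubiquitin and proteasome genes were slightly higher, with a median of 0.07 (adjusted p = 0.0114, camera, and adjusted p = 0.379 with an estimated correlation), and Psmd12 stood at 0.23. Cholesterol synthesis genes had a median of 0.12 (adjusted p = 0.0247, camera, and adjusted p = 0.413 with an estimated correlation), with Stard4 at 0.31 and Msmo1 at 0.40, while the regulator Srebf2 stood at -0.41. No member of either list passed over its list alone. The proteasome list was lost without ICI replicate 2, at a median of 0.04, and had the same median without oil replicate 1. The cholesterol list was lost without ICI replicate 2, at 0.04, and without oil replicate 1, at 0.08, and its median was 0.21 without ICI replicate 1. It was 0.05 with the mean of probe sets and 0.07 without cross-hybridising ones, and was lost with both.

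The remaining lists did not pass. Ribosome biogenesis had a median of 0.05 (adjusted p = 0.0891, camera), with Nop58 at 0.37 and Rrs1 at 0.28 rising over the list alone, and it passed without oil replicate 2 (adjusted p = 0.0215, camera), without a filter and with the mean of probe sets. Adjusted camera p-values were 0.306 for oviduct ciliated cell markers, 0.574 for fat cell markers, 0.69 for mast cell markers and 0.841 for neutrophil and eosinophil markers. They were 0.713 for clock genes and for genes of RNA quality and stress, 0.762 for glycolysis, 0.779 for skeletal muscle markers and 0.877 for protein folding in the endoplasmic reticulum. They were 0.957 for apoptosis and for uterine gland markers, 0.958 for chemokines and cytokines, and 0.988 for angiogenesis and hypoxia. In the gland list Guca2b, encoding uroguanylin, fell over the list alone at -1.39. The median and the direction of the test differed in sign for mast cell and gland markers. The median and the mean differed in sign for gland markers, apoptosis, chemokines and angiogenesis. Only 2 red blood cell markers were measured, Bpgm at 0.08 and Hbb-b2 at -0.16, too few for a test.

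Of the 39 lists tested, 16 passed, 4 higher and 12 lower, and 14 did so with ranks. Several of the 12 share measured genes and are not separate findings. The late estrogen-induced list shared 4 with water and ion transport, 3 with complement and 2 with epithelium markers. The early list shared 5 with the immediate early genes. With an estimated correlation 0 passed by camera, with 2 at an unadjusted p under 0.05. By fry 0 passed, with 9 at that p, while 11 passed fry's mixed test of change in either direction. DNA replication was among the 11 (adjusted p = 0.0272, fry mixed), but mitosis (0.0722) and the late estrogen-induced genes (0.0622) were not. The 11 included lists that camera did not call, such as the hedgehog (0.00697) and Wnt (0.00981) pathways. The preset correlation also called lists between arrays that the labels do not separate: 7 lists, DNA replication among them (adjusted p = 0.0219), for the replicate 1 arrays against the replicate 2 arrays, and 2, mitosis and endothelium, for oil replicate 1 with ICI replicate 2 against the others. In that last grouping mitosis had an adjusted p of 0.0055 (camera) and a median of 0.20.

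**Figure D3:**
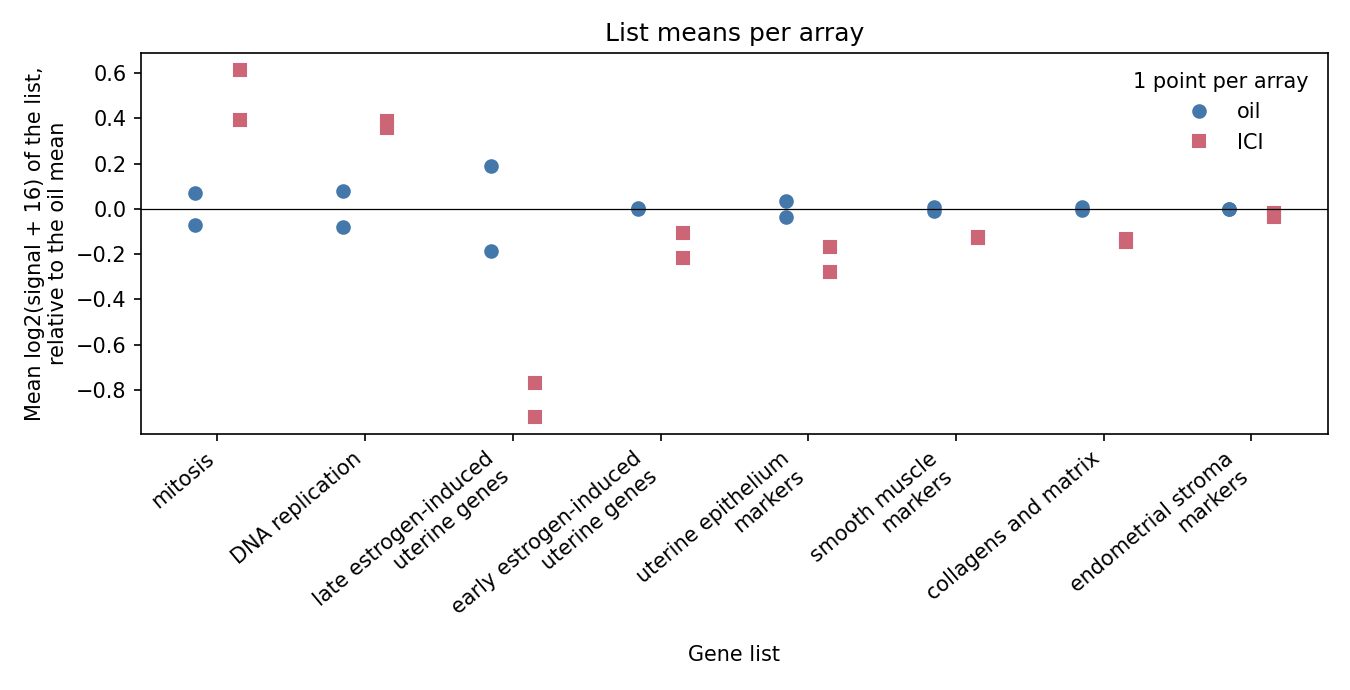
Mean log2(signal + 16) of 8 gene lists on each array, relative to the mean of the oil arrays; circles are oil arrays and squares ICI arrays. The ICI arrays lie at 0.61 and 0.39 for mitosis, at 0.36 and 0.39 for DNA replication and at -0.77 and -0.92 for the late estrogen-induced genes, while the oil arrays lie within 0.19 of 0 for all 8 lists.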

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

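No called gene or list that was followed turned its sign under the alternatives run for it. Among lists that did not pass, quantile normalization turned the median to 0.02 for breast cancer estrogen targets, 0.01 for the stroma growth factors and 0.02 for clock genes, and the median shift turned that of mast cell markers below 0. The median of the 2 red blood cell markers, which were not tested, turned to 0.03 with quantile normalization. Of the called genes 68.4% were lower, against 43% with the replicate block and 42.9% without oil replicate 2. The fit without cross-hybridising probe sets was chosen after seeing the data, and the cause of each change was not tested unless stated. The 19 called genes became 41 at an adjusted p under 0.1, 12 over all probe sets, 0 by eBayes without the trend (1132 at an unadjusted p under 0.05), 1 with the mean of a gene's probe sets, 38 with a median shift, 1 without a filter and 10 without cross-hybridising probe sets. Leaving out each array in turn gave 38 to 133, where the lone array is assumed to vary like the other group's pair. Single genes were followed in up to 13 alternatives, which leave out the fits on all or averaged probe sets. There Uhrf1, Mcm6, Tcf19, Prune2, Inhbb, Alox15, Clca1, Aoc1 and Sftpd lost their calls only without the trend and without a filter, and Prap1 only without the trend. The other 9 also lost theirs when cross-hybridising probe sets were left out. Of these, Ltf, Lcn2, Calb2, Cd36, Pcdhb9 and Mamdc2 kept their probe set and log2 change (Ltf -1.58, Lcn2 -2.23), with adjusted p from 0.056 to 0.0609, while Kif22, Rrm2 and Mcm5 passed to another probe set. With quantile normalization 2 of the 9 were lost, and 3 with an ICI array left out. The replicate numbers do not pair the arrays as far as the labels say, and the differences between replicates correlated at 0.0614 across genes between the groups. With replicate number as a block 344 genes were called, 196 higher and 148 lower, and 2 matrix and 8 muscle genes fell over their list alone.

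The 244 genes of the fold rule became 580 over all probe sets, 96 with the stricter filter, 46 at a fold of 2, 599 without a filter, 137 with an offset of 64, and 308 to 377 with an array left out. The 16 lists became 0 with an estimated correlation and 0 with fry, and 13 to 17 with an array left out. The SD between replicates rose from 0.271 to 0.476 without a filter, which admits dim probe sets with noisy MAS5 signals. Nr2f2 stayed below the threshold in all 6 alternatives run for it. Beyond the losses given with each list, implantation genes did not pass with ranks or averaged probe sets, mesothelium with ranks, without the trend or without a filter, immediate early genes with the stricter filter, the proteasome without the trend, and cholesterol synthesis with averaged or without cross-hybridising probe sets. With the mean of a gene's probe sets the mitosis genes that rose over the list alone numbered 11.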

Other observations

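The tests below were chosen after results had been seen, apart from that of array scaling for the cell cycle genes, whose matching was refined afterwards, and that of oil replicate 1. The gene families were picked after their values were seen, so their p-values describe them and do not test them. The third pattern replaced a difference between the oil arrays that had been weighed earlier. The 95% intervals below come from resampling the genes of a set, so they measure the spread over genes and not between samples.

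The granzymes, serine proteases of cytotoxic granules that uterine NK cells also make, were lower for all 7 measured members, with a median of -1.18. All 7 fell when adjusted over the family alone and 0 over all genes tested (limma). The family passed camera with an adjusted p of 2.16e-08 over 9 families, and had an unadjusted p of 0.127 with an estimated correlation. Gzmf had signals of 306.7 and 176.6 on the oil arrays and 111.3 and 11.8 on the ICI arrays, and Gzmc 265.8 and 176.5 against 111.9 and 66.6. ICI replicate 2 had the lower value for each of the 7, and without it 4 fell, with a median of -0.72. Without the variance trend 0 of the 7 fell. With the filter at the 60th percentile 3 members remained, with a median of -0.58. Gzmd and Gzme, at -1.94 and -1.50, are near-identical paralogs read by probe sets that can cross-hybridise. Gzma and Gzmb are also on the lymphocyte and NK list.

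Of the centromere proteins 17 of 20 were higher, with a median of 0.33 (adjusted p = 4.57e-06, camera, and unadjusted p = 0.144 with an estimated correlation). Over the family alone 3 rose, against 0 over all genes tested, and that count was 0 with the mean of probe sets and 5 without oil replicate 2. Without oil replicate 1 the median was 0.15 and with the mean of probe sets 0.21. Cenpa and Cenpe are also on the mitosis list. Cenpf stood at 0.77, Cenpk at 0.89 and Cenpp at 0.91. The 3 measured peptidylarginine deiminases, Padi1, Padi2 and Padi4, were at -0.90, -0.90 and -1.23, and each fell over the family alone, all 3 being also on the late estrogen-induced list. Of 15 clustered protocadherin beta genes Pcdhb9 was the 1 that fell over the family alone, and the family's median was 0.02. That median turned to -0.021 without oil replicate 2, -0.015 without ICI replicate 2 and -0.001 without a filter. Minichromosome maintenance proteins were higher for 8 of 9 (adjusted p = 1.03e-06, camera; unadjusted p = 0.0328 with an estimated correlation), and 7 of the 9 are also on the DNA replication list. Keratins, zinc finger proteins and solute carriers did not pass, with adjusted camera p-values of 0.195, 0.306 and 0.38. Ribosomal proteins were lower for 36 of 41, with a median of -0.12 (adjusted p = 6.89e-06, camera; unadjusted p = 0.343 with an estimated correlation). A median as low was found in 1370 of 10000 random lists matched on signal. Those lists could draw other ribosomal proteins, so this share cannot decide on array scaling of bright genes, which remains open for this family.

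The cell cycle genes, 56 in the mitosis and replication lists, were higher after the antagonist with a median of 0.45. If scaling that depends on intensity were the source, random lists of like signal would share the shift, but 0 of 10000 reached it and the highest of their medians was 0.0989. If a tissue layer such as muscle had simply made up less of the ICI samples, markers of stroma and endothelium would have risen alike, but their median was 0.00067635 (95% interval -0.08 to 0.03) against 0.39 to 0.50 for the cell cycle genes. That cells differed in cycle phase or that more were cycling is a hypothesis that these arrays cannot separate from a difference between the samples unrelated to the antagonist, since mitosis genes also differed, by a median of 0.20, between arrays that the labels do not separate.

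The late estrogen-induced genes had a median of -0.40 (95% interval -1.12 to -0.03, 18 genes). A smaller share of epithelium in the ICI samples would lower other epithelium markers alike. The median of 21 such markers was -0.140452 (-0.27 to -0.07), inside that interval, so a smaller share stays open for the list as a whole. High values on oil replicate 1 alone were tested by leaving it out, and the list stayed lower with a median of -0.34 and an adjusted p of 1.28e-11 (camera; 1.02e-30 to 0.379 over all alternatives). Of the 10 genes that fell over the list alone, 9 were higher on oil replicate 1 than on oil replicate 2, and 10 on ICI replicate 1 than on ICI replicate 2. Loss of estrogen receptor activity is the explanation that the design names, and it too stays open as a hypothesis.

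Matrix and smooth muscle genes were lower by a small amount, with a median of -0.17 over 51 genes and lower means for 84.3%. Bright genes in general leaned the same way, with 58.8% of the top 5% by signal lower and a median of -0.03, which turned to 0.00 with quantile normalization. Scaling could account for part of it, since that normalization moved the matrix and muscle median to -0.11, but 0 of 10000 matched lists were as low. A smaller share of stroma would lower other stroma markers too, and the median of 14 outside the matrix list was 0.00659302 (-0.08 to 0.08), against -0.19 to -0.13. Unlike the epithelium markers above, these 14 were not cleared of hormone-list genes. They include 4 of the progesterone-induced list, Hand2 at 0.35, Wnt5a at 0.20, Hoxa11 at 0.02 and Hoxa10 at -0.07. A lower share of muscle, or reduced transcription in both layers, was not tested for this pattern and remains open. The stroma and endothelium markers above were set only against the larger rise of the cell cycle genes.

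Among probe sets without a gene symbol 4066 were tested, 0 passed in limma and 426 had an unadjusted p under 0.05. Grouping the arrays by replicate number called 0 genes, with 446 at that p, and the third grouping called 1, with 271. With 3 such groupings no share under 0.05 can be had, the real count being 19 and the highest other 1.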
